A study of Homo sapiens with 24 samples.

How the data were processed

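RNA-seq was made from total RNA of HBL-1 cells grown in RPMI-1640 with 20% fetal calf serum, extracted with the Qiagen RNeasy Mini kit and sequenced by a standard Illumina protocol, per the labels' protocols. There were 24 libraries, 3 for each of DMF and control at 6, 12, 24 and 48 h, with 1 deposited gene table per library. Reads were aligned and genes quantified with HISAT2, HISAT and RSEM on GRCh38.p12, per the submitters' processing notes, which gave no tool versions. The deposited tables held RSEM's expected counts, which are estimated reads per gene without normalization. Between 6.16% and 11.53% of these were not whole numbers. The deposited TPM values, scaled by effective length to a fixed sum per library, served for 1 alternative and the deposited FPKM values for no result. Gene and effective lengths in bases were those of the tables, per the file headers. The strand used in counting was not stated. Gene names were RefSeq symbols, with 21831 genes in each table. Second copies of 21 pseudoautosomal genes were kept as separate genes. Coordinates and the GC content of transcripts came from GENCODE v29, matched by symbol.

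Expected counts were rounded to whole numbers. Genes were filtered with filterByExpr by group (13419 of 21831 kept) and scaled by TMM in edgeR 4.0.16 (R 4.3.3). Genes of ribosomal RNA stayed in, with 0.645% to 2.461% of counts per library. This share was higher in every DMF library than in every control at 6, 24 and 48 h, but not at 12 h. In control and DMF it was 1.004% to 1.087% and 1.723% to 1.893% at 6 h. At 24 h it was 0.645% to 0.682% and 0.915% to 0.919%, and at 48 h 0.728% to 0.793% and 1.287% to 1.448%. The cause was not tested. A single quasi-likelihood fit of all 24 libraries had 1 mean for each of the 8 groups and 16 residual degrees of freedom. F-tests compared DMF with control at each time, the effects of DMF between times (3 interaction contrasts jointly, and 4 pairs of times), and control at 12, 24 and 48 h with control at 6 h. P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were the absolute value divided by the square root of F. CPM are counts per 1000000 after TMM scaling unless stated, and folds are 2 to the power of the log2 fold change, or ratios of sums for the CCL3 and CCL4 families. Depth limited precision most in replicate 1 of DMF at 48 h, with 2870751 counts. No library was removed from these fits.

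Gene lists were written without knowledge of the values, for 25 processes or cell types, and were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation between genes of 0.01. Adjustment was over the lists of each comparison. Lists overlap, as the NRF2, ATF4, ferroptosis, glutathione and iron lists share genes. Beside the number of members called among all genes, the text gives the number after adjustment over the list alone and the number in the 22 libraries. Medians are those of the fit of all 24 libraries, so at 12 h they include the replicate 3 libraries that stood apart. Named genes were drawn under a rule fixed in advance. It admits a panel of 32 genes for the antioxidant, stress, NF-kB and STAT3 responses, and at each time the 10 highest and 10 lowest log2 fold changes among called genes with at least 1 CPM in the higher group and all DMF libraries on one side of the controls. The rule asked for the panel at every time whatever its result, but the text gives only some of its genes and times. It also admits up to 4 members of each list with the smallest p at each time, the 10 smallest p of the joint test, and the 5 highest and 5 lowest changes in control from 6 to 48 h. GARS and MARS are the tables' symbols for GARS1 and MARS1. Cell-type markers (CD8A, CD68, EPCAM) came from the marker lists. The copies CCL3L3 and CCL4L2 were added after the values were seen.

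The steps were tested on simulated data with 200 changed genes, drawn with the means of control at 6 h and the library sizes and dispersions of these libraries. Counts were drawn independently for each library, so no simulated library carried the deviation of the replicate 3 libraries of 12 h. The false calls therefore do not measure those of the real comparison at 12 h. With the spread of all libraries, changes of 1.5-fold, 2-fold and 4-fold were recovered for 26.9%, 61.2% and 95.5% of genes at 6 h (13030 tested), 17.9%, 67.2% and 100% at 12 h, 22.4%, 71.6% and 92.4% at 24 h, and 17.9%, 61.2% and 92.4% at 48 h. With the spread of the 22 libraries (13122 tested) the shares were 88.1%, 100% and 100% at 6 h and 82.1%, 95.5% and 100% at 48 h. False calls numbered 4, 7, 10 and 3 at the 4 times with all libraries, and 10, 8, 10 and 12 with the 22.

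Alternatives fixed in advance were DESeq2's size factors in edgeR, no low-count filter (18123 genes with at least 1 count), DESeq2 1.42.0, a replicate block, fits of only the groups compared, limma with trend on log2(TPM + 1) for 11655 genes with a mean of at least 1 TPM in any group, camera with an estimated correlation, fry, and leaving out each library in turn. Alternatives chosen after seeing the data were the 22 libraries without replicate 3 of 12 h (13606 genes tested), and several fits built on it. The fit on TPM used no TMM scaling. For checks across libraries, genes with a mean log2 CPM of at least 3 were used. Tables were read and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.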

Results

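HBL-1, an established human cell line of activated B-cell-like diffuse large B-cell lymphoma, was cultured with 20 µM dimethyl fumarate (DMF) dissolved in DMSO or with DMSO alone (control). DMF is an electrophilic ester of fumaric acid that reacts with cysteine residues and activates NRF2, the transcription factor of the antioxidant response. Cells were taken after 6, 12, 24 and 48 h, with 3 libraries for each treatment and time, which gave 24 RNA-seq libraries in 8 groups. The deposited tables listed 21831 genes. Total expected counts ranged from 2870751 in replicate 1 of DMF at 48 h to 40906596. The second-lowest total was 23097873. Between 13103 and 15526 genes had counts in a library.

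The replicate 3 libraries of 12 h, control and DMF, stood apart from the others. Their mean effective transcript length weighted by counts was 1902 and 2121 bases, against 2850 to 3157 bases in the other libraries. Transcripts of ribosomal proteins took 24.19% of counts in the control library and 19.05% in the DMF library, against 8.0% to 12.81% elsewhere. Both libraries were kept, as the design was fixed before the data were examined. Counts of called genes are therefore also given for the 22 libraries other than these, an alternative chosen after seeing the data. The common dispersion was 0.0521 with all 24 libraries and 0.00212 with the 22. Every p-value measures only the spread between libraries labelled replicates, which may be technical.

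**Figure D1:**
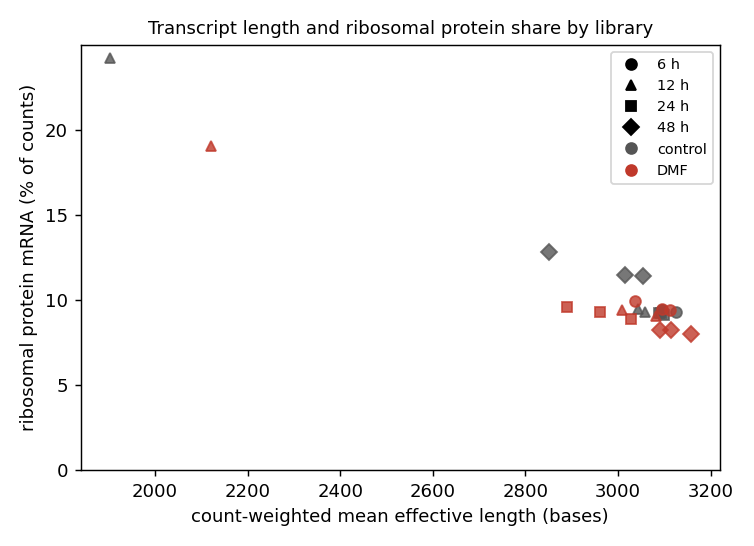
Mean effective transcript length weighted by counts (bases) against the percent of counts from ribosomal-protein transcripts, 1 point per library, with control in grey, DMF in red and a symbol for each time. Replicate 3 of 12 h held 24.19% and 19.05%.

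The series title concerns ferroptosis, an iron-dependent form of cell death, and the NF-kB and STAT3 pathways, so gene lists for these and for stress responses were fixed before the data were examined. The comparison at 6 h asked what DMF changed at the earliest time sampled. Antioxidant genes had the highest median of the lists: 17 of the 28 measured NRF2 targets rose (22 adjusted over the list alone, 25 in the 22 libraries, camera adjusted p = 1.9e-23, median log2 fold change 1.17). OSGIN1, an oxidative stress response gene on chromosome 16, 83948282 to 83966332 (GRCh38), rose 37.3-fold (log2 fold change 5.22 ± 0.39, adjusted p = 4.6e-08), from 0.934 ± 0.148 to 35.2 ± 2.07 CPM (mean ± SD, n = 3). SRXN1, which encodes sulfiredoxin, rose 9.89-fold (log2 fold change 3.31 ± 0.16, adjusted p = 1.7e-10), from 35.0 ± 1.18 to 346 ± 4.54 CPM. HMOX1, the heme oxygenase gene, rose 4.26-fold (log2 fold change 2.09 ± 0.13, adjusted p = 5.7e-09). SLC7A11, the cystine carrier of the plasma membrane, rose 4.16-fold (log2 fold change 2.06 ± 0.24, adjusted p = 9.9e-06). NQO1, a quinone reductase, rose 4.88-fold (log2 fold change 2.29 ± 0.20, adjusted p = 3.5e-07). The glutathione synthesis enzyme gene GCLM and the thioredoxin reductase gene TXNRD1 rose 4.32-fold and 4.53-fold. In each log2 fold change, the value after ± is the standard error from the edgeR fit of 3 libraries per group.

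Genes induced by the stress factor ATF4 rose at 6 h, 24 of 35 measured (29 up and 1 down over the list alone, 34 up and 1 down in the 22 libraries, camera adjusted p = 2.2e-29, median 0.79). Among them, SESN2, which encodes a sestrin that restrains mTORC1, rose 2.55-fold (log2 fold change 1.35 ± 0.07, adjusted p = 2.4e-10). CHAC1, a glutathione-degrading enzyme, rose 2.77-fold (log2 fold change 1.47 ± 0.16, adjusted p = 4.3e-06). The amino acid transporter gene SLC7A5, the transaminase gene GPT2 and the pseudokinase gene TRIB3 rose 2.16-fold, 2.40-fold and 1.69-fold. Heat shock genes rose as well, 10 of 20 (16 over the list alone, 19 in the 22 libraries, camera adjusted p = 1.7e-13, median 0.51). HSPA1B, an inducible HSP70 gene, rose 5.27-fold (log2 fold change 2.40 ± 0.11, adjusted p = 4.7e-11), from 19.2 ± 1.26 to 101 ± 2.35 CPM. DNAJB1, a co-chaperone of HSP70, rose 2.89-fold and BAG3, another, rose 2.63-fold. HSPA1B and HSPA1A encode near-identical transcripts, so how RSEM divided reads between them is uncertain. Of the 20 measured genes of the unfolded protein response of the endoplasmic reticulum, 6 rose (7 over the list alone, 18 in the 22 libraries, camera adjusted p = 1.5e-07, median 0.49), among them XBP1 (1.73-fold), HSPA5 (1.52-fold) and HERPUD1 (1.45-fold).

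Of the 26 measured ferroptosis-related genes, 9 rose and 1 fell at 6 h (10 and 2 over the list alone, 15 and 4 in the 22 libraries, camera adjusted p = 0.00017, median 0.31). Those that rose included SLC7A11, HMOX1, GCLM and CHAC1, which the NRF2 and ATF4 lists also hold. Log2 fold changes at 6 h were 0.01 for GPX4 (adjusted p = 1), the peroxidase that removes lipid peroxides, 0.08 for ACSL4 (adjusted p = 0.96), which loads polyunsaturated fatty acids into lipids, and 0.30 for TFRC (adjusted p = 0.63), the transferrin receptor. They were 0.01 (adjusted p = 0.95), 0.08 (adjusted p = 0.16) and 0.30 (adjusted p = 2.1e-05) in the 22 libraries. For glutathione synthesis and use, 5 of 23 genes rose and 1 fell (5 and 1 over the list alone, 8 and 5 in the 22 libraries, camera adjusted p = 0.024, median 0.10, adjusted p = 0.32 with an estimated correlation). In the iron handling list 3 of 19 rose and 1 fell (3 and 1 over the list alone, 8 and 3 in the 22 libraries, camera adjusted p = 0.12, median 0.08). The list was called higher in the 22 libraries, also with an estimated correlation (adjusted p = 0.046).

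Interferon-response genes were lower at 6 h: 10 of 20 fell (13 over the list alone, 15 in the 22 libraries, camera adjusted p = 2.1e-09, median -0.93). XAF1, an interferon-induced gene, fell 4.39-fold (log2 fold change -2.13 ± 0.30, adjusted p = 6.9e-05). DDX58, which encodes the RNA sensor RIG-I, fell 2.58-fold. TNFSF10, the gene of the death ligand TRAIL, fell 4.22-fold, from 1.15 ± 0.296 to 0.268 ± 0.0325 CPM. NF-kB targets went both ways, 4 up and 7 down of 30 (4 and 10 over the list alone, 7 and 16 in the 22 libraries, camera adjusted p = 0.15, median -0.25). CD40, a receptor that activates NF-kB, fell 2.09-fold (log2 fold change -1.06 ± 0.14, adjusted p = 3.4e-05), and TNFAIP3, the feedback inhibitor A20, had a log2 fold change of -0.76 (adjusted p = 0.2), which was -0.76 (adjusted p = 6.9e-13) in the 22 libraries. The NF-kB list was called lower in the 22 libraries, though not with an estimated correlation there (adjusted p = 0.12), and TNFAIP3 without control 12 h replicate 3. The chemokine genes CCL3 and CCL4 rose instead. CCL4 (GRCh38 chromosome 17, 36103590 to 36105621) rose 9.68-fold (log2 fold change 3.27 ± 0.22, adjusted p = 7.9e-09), from 2.39 ± 0.528 to 23.1 ± 0.657 CPM. CCL3 rose 9.13-fold. Both have near-identical copies (CCL3L3 and CCL4L2), and the counts summed over a gene and its copy rose 9.60-fold and 9.41-fold at 6 h. Of the 16 measured STAT3 targets, 3 rose and 2 fell (3 and 2 over the list alone, 5 and 5 in the 22 libraries, camera adjusted p = 0.71, median 0.04). SOCS3, a feedback inhibitor of STAT3 signalling, fell 2.78-fold (log2 fold change -1.48 ± 0.23, adjusted p = 0.0002), while IL10 rose 1.68-fold (log2 fold change 0.75 ± 0.15, adjusted p = 0.002), from 4.04 ± 0.212 to 6.79 ± 0.616 CPM.

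Smaller shifts at 6 h concerned B cell, plasma cell and cell cycle genes. In the list of B cell identity and B cell receptor signalling, 1 of 24 rose and 3 fell (1 and 3 over the list alone, 5 and 13 in the 22 libraries, camera adjusted p = 0.044, median -0.13, adjusted p = 0.058 with an estimated correlation). SYK, the kinase downstream of the B cell receptor, fell 1.52-fold (log2 fold change -0.61 ± 0.08, adjusted p = 4.6e-05). Of 12 plasma cell genes 3 rose and 1 fell (4 and 1 over the list alone, 5 and 3 in the 22 libraries, camera adjusted p = 0.025, median 0.20). SLAMF7, a plasma cell surface receptor, rose 3.02-fold (log2 fold change 1.59 ± 0.10, adjusted p = 2.3e-09). PRDM1, the regulator BLIMP1, rose 2.41-fold. CD38, another surface marker of plasma cells, fell 2.10-fold. Mitosis genes had 2 of 20 up (2 over the list alone, 11 up and 2 down in the 22 libraries, camera adjusted p = 0.042, median 0.12, adjusted p = 0.28 with an estimated correlation). DNA replication genes had 1 up and 3 down of 20 (1 and 3 over the list alone, 1 and 15 in the 22 libraries, camera adjusted p = 0.032, median -0.16, adjusted p = 0.1 with an estimated correlation). For cholesterol synthesis 2 of 22 rose (3 over the list alone, 11 up and 1 down in the 22 libraries, camera adjusted p = 0.015, median 0.12, adjusted p = 0.094 with an estimated correlation in the 22 libraries), IDI1 by 1.65-fold. The plasma cell call ended in the 22 libraries. Leaving out 1 library ended the mitosis call for control 6 h replicate 2, DMF 6 h replicates 1 and 2, control 24 h replicates 1, 2 and 3, DMF 24 h replicate 3, control 48 h replicate 2 and DMF 48 h replicates 2 and 3. It ended the B cell call for each library except replicate 1 of control 6 h, replicate 3 of control 12 h, replicates 1 and 3 of control 48 h and replicates 1 and 3 of DMF 12 h.

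By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 675 genes were higher and 750 lower in DMF at 6 h, of 13419 tested, and 182 and 214 of these differed at least 2-fold. In the 22 libraries 3242 were higher and 3179 lower, 260 and 321 at least 2-fold, and all 1425 calls kept their direction and their side of the threshold. The libraries of 6 h were the same in both fits and only the estimated spread was lower, so this does not test these calls. All 3 DMF libraries lay on one side of all 3 controls for 59.9% of genes tested, where chance gives 10% if the libraries of that time are exchangeable. If the libraries of a group came from the same culture, any difference between cultures would also raise this share. Without control 12 h replicate 3 the counts were 1242 and 1403, and 482 or 499 genes were lower without DMF 6 h replicate 1 or 2. On TPM, limma called 240 higher and 724 lower genes, 24.9% higher against 47.4%, and no longer called SLC7A5, BAG3, XBP1, HSPA5, HERPUD1, IL10, CD38 and IDI1.

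The comparison at 12 h repeated this at the next time. Antioxidant genes were higher again, 19 of 28 NRF2 targets (20 over the list alone, 25 in the 22 libraries, camera adjusted p = 2.5e-17, median 0.88). OSGIN1 rose 68.8-fold (log2 fold change 6.11 ± 0.42, adjusted p = 8.9e-09). OSGIN1 had a log2 fold change of 6.77 without control 12 h replicate 3, 5.51 without DMF 12 h replicate 3 and 6.19 in the 22 libraries. NQO1 rose 8.57-fold (log2 fold change 3.10 ± 0.21, adjusted p = 7.5e-09). HMOX1 rose 6.00-fold (log2 fold change 2.59 ± 0.14, adjusted p = 4.1e-10). SQSTM1, the autophagy receptor p62, rose 3.97-fold. MAP1A, which encodes a microtubule-associated protein (GRCh38 chromosome 15, 43510958 to 43531620), rose 13.8-fold (log2 fold change 3.79 ± 0.28, adjusted p = 2.8e-08), from 1.95 ± 0.567 to 27.2 ± 9.45 CPM. GABARAPL1, an autophagy gene, rose 7.12-fold. ADM, the gene of the peptide adrenomedullin, rose 3.55-fold. Heat shock genes rose, 12 of 20 (15 over the list alone, 17 up and 2 down in the 22 libraries, camera adjusted p = 1.9e-08, median 0.48). Unfolded protein response genes rose too, 10 of 20 (10 over the list alone, 20 in the 22 libraries, camera adjusted p = 5.8e-07, median 0.37), HSPA5 by 1.52-fold. In the ATF4 list 8 of 35 rose and 1 fell (10 and 1 over the list alone, 18 and 5 in the 22 libraries, camera adjusted p = 0.0042, median 0.25, adjusted p = 0.08 with an estimated correlation in the 22 libraries), with SLC7A5 up 1.47-fold and JDP2, a bZIP factor, down 1.46-fold.

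Among ferroptosis-related genes at 12 h, 8 of 26 rose and 2 fell (9 and 3 over the list alone, 16 and 5 in the 22 libraries, camera adjusted p = 0.017, median 0.28, adjusted p = 0.18 with an estimated correlation). FTL, the ferritin light chain gene, rose 3.62-fold (log2 fold change 1.86 ± 0.37, adjusted p = 0.0013), although its many pseudogenes make the count uncertain. Without control 12 h replicate 3 the log2 fold change of FTL was 2.70, and in the 22 libraries it was 2.20. ALOX5, a lipoxygenase gene, fell 3.67-fold (log2 fold change -1.87 ± 0.12, adjusted p = 4.8e-09). The ferroptosis list's call ended without control 12 h replicate 1 or 2 or DMF 12 h replicate 3. Log2 fold changes were -0.46 for GPX4 (adjusted p = 0.61), 0.29 for ACSL4 (adjusted p = 0.6) and 0.38 for TFRC (adjusted p = 0.38). They were 0.04 (adjusted p = 0.69), 0.21 (adjusted p = 0.0019) and 0.33 (adjusted p = 8.3e-05) in the 22 libraries. The value for GPX4 rested on the replicate 3 libraries of 12 h, at 0.83 without that of control and -1.27 without that of DMF, and it was called in neither case. Those of ACSL4 and TFRC were -0.09 and 0.05 without control 12 h replicate 3. The glutathione list had 4 of 23 up and 3 down (4 and 6 over the list alone, 8 and 9 in the 22 libraries, camera adjusted p = 0.95, median -0.23, with camera's direction up). The iron list had 4 up and 2 down of 19 (4 and 2 over the list alone, 7 and 2 in the 22 libraries, camera adjusted p = 0.092, median 0.07). TFRC was called higher without DMF 12 h replicate 3 (0.65), and the iron list was in the 22 libraries, also with an estimated correlation (adjusted p = 0.041).

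NF-kB targets were lower at 12 h: 16 of 30 fell and 2 rose (2 up and 16 down over the list alone, 4 up and 21 down in the 22 libraries, camera adjusted p = 1.5e-05, median -0.61). NFKBIA, the inhibitor of NF-kB (GRCh38 chromosome 14, 35401511 to 35404749), fell 2.13-fold (log2 fold change -1.09 ± 0.13, adjusted p = 1.2e-05). CD40 fell 2.71-fold (log2 fold change -1.44 ± 0.14, adjusted p = 7.7e-07), and the adhesion molecule gene ICAM1 fell 1.60-fold. CCL17, a chemokine gene, had a log2 fold change of -2.98, which was -1.77 without control 12 h replicate 3 and -2.22 in the 22 libraries. CCL3 and CCL4 rose 6.23-fold and 10.7-fold. Of the interferon-response genes, 13 of 20 fell (16 over the list alone, 18 in the 22 libraries, camera adjusted p = 2.7e-11, median -1.40). IFIH1, the RNA sensor MDA5, fell 5.94-fold (log2 fold change -2.57 ± 0.23, adjusted p = 3.8e-07), from 6.97 ± 0.996 to 1.15 ± 0.382 CPM, and MX1 and OAS1 fell 2.51-fold and 3.17-fold. STAT3 targets had 2 of 16 down (1 over the list alone, 2 up and 6 down in the 22 libraries, camera adjusted p = 0.53, median -0.10). SOCS3 fell 3.19-fold (log2 fold change -1.67 ± 0.23, adjusted p = 5.3e-05). B cell genes had 7 of 24 down and 1 up (2 up and 8 down over the list alone, 6 up and 14 down in the 22 libraries, camera adjusted p = 0.0081, median -0.28), with POU2AF1, a B cell coactivator, down 1.67-fold. DNA replication genes fell, 10 of 20 (11 over the list alone, 18 in the 22 libraries, camera adjusted p = 1.2e-05, median -0.38), such as CDC45 (1.89-fold), TYMS (1.32-fold) and PCNA (1.46-fold). Mitosis genes had 3 of 20 up (3 over the list alone, 8 in the 22 libraries, camera adjusted p = 0.022, median 0.10, adjusted p = 0.21 with an estimated correlation). This call ended in the 22 libraries and without control 12 h replicate 3. Hypoxia and glycolysis genes had 3 of 20 up (3 over the list alone, 12 up and 2 down in the 22 libraries, camera adjusted p = 0.03, median 0.20, adjusted p = 0.14 with an estimated correlation). This call ended without replicate 1 or 3 of control 12 h or replicate 3 of DMF 12 h.

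At 12 h, 989 genes were higher and 1335 lower in DMF by edgeR's test, 185 and 558 at least 2-fold. The DMF libraries lay on one side of the controls for 16.7% of genes tested (10% for exchangeable libraries). In the 22 libraries 3277 were higher and 3238 lower, 272 and 603 at least 2-fold, and 2268 of the 2324 calls were kept in direction and side of the threshold. Without control 12 h replicate 3 the counts were 2194 and 2150. When DMF 12 h replicate 3 was left out, 2367 genes were lower. In a fit of the 6 libraries of 12 h alone, edgeR called 0 genes, with 1109 at an unadjusted p under 0.05, while DESeq2 on all libraries called 1290 higher and 1474 lower. On TPM, limma called 377 higher and 795 lower, 32.2% higher against 42.6%, and no longer called HSPA5, SLC7A5, JDP2, NFKBIA, ICAM1, POU2AF1, TYMS and PCNA.

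At 24 h antioxidant genes were still higher, 16 of 28 NRF2 targets (22 up and 2 down over the list alone, 23 and 4 in the 22 libraries, camera adjusted p = 4.4e-12, median 0.83). NQO1 (GRCh38 chromosome 16, 69706996 to 69726951) rose 12.0-fold (log2 fold change 3.59 ± 0.21, adjusted p = 3.0e-09). HMOX1 rose 3.74-fold (log2 fold change 1.90 ± 0.13, adjusted p = 2.2e-08). At 24 h HMOX1 stood at 24.5 to 26.9 CPM in control and 93.3 to 101 CPM in DMF. Both lay below the 176 to 194 CPM of control at 6 h. OSGIN1 rose 36.1-fold and FTL rose 6.13-fold. The ATF4 list was lower at 24 h: 20 of 35 genes fell and 1 rose (1 up and 25 down over the list alone, 3 up and 29 down in the 22 libraries, camera adjusted p = 1.9e-15, median -0.62). SESN2 fell 1.47-fold (log2 fold change -0.56 ± 0.07, adjusted p = 1.3e-05), from 68.4 ± 2.19 to 46.5 ± 0.679 CPM. CHAC1 fell 1.89-fold (log2 fold change -0.92 ± 0.16, adjusted p = 0.00044), and the serine synthesis gene PSAT1 fell 2.25-fold. JDP2 fell 2.29-fold, and the tRNA synthetase genes GARS and MARS fell 1.59-fold and 1.57-fold. SLC7A11, which had been higher at 6 h, had a log2 fold change of -0.62 (adjusted p = 0.093), and was called lower when a replicate 3 library of 12 h, control or DMF, was left out. Heat shock genes had 4 of 20 up and 1 down (4 and 1 over the list alone, 11 and 4 in the 22 libraries, camera adjusted p = 0.19, median 0.18), with HSPA1B up 1.5-fold and HSPA8, the constitutive HSC70 gene, down 1.58-fold. The unfolded protein response list had 1 of 20 up at 24 h (0 and 0 over the list alone, 15 and 2 in the 22 libraries, camera adjusted p = 0.081, median 0.16). It was called higher in the 22 libraries, though not with an estimated correlation there (adjusted p = 0.079), and without control 12 h replicate 3. Metallothioneins, which bind zinc and copper, and a zinc exporter had 2 of 4 up (4 over the list alone, 4 in the 22 libraries, camera adjusted p = 0.0069, median 1.38, adjusted p = 0.079 with an estimated correlation in the 22 libraries), MT1X by 3.75-fold, although the close sequences of this family make single genes uncertain. Against control at 6 h the list median at 24 h was -1.66 in control and -0.17 in DMF, and at 48 h it was -0.04 in control and 0.57 in DMF.

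NF-kB and STAT3 targets were lower at 24 h. Of the NF-kB targets 16 of 30 fell and 3 rose (3 up and 18 down over the list alone, 4 up and 22 down in the 22 libraries, camera adjusted p = 1.7e-09, median -0.80). NFKBIA fell 2.24-fold (log2 fold change -1.16 ± 0.13, adjusted p = 7.4e-06). TNFAIP3 fell 2.80-fold (log2 fold change -1.48 ± 0.35, adjusted p = 0.0065). ICAM1 fell 2.06-fold (log2 fold change -1.04 ± 0.08, adjusted p = 5.2e-08). CFLAR, an inhibitor of death receptor signalling, fell 1.76-fold. CCL4 rose 8.73-fold (log2 fold change 3.13 ± 0.22, adjusted p = 2.2e-08). CD83, a surface marker of activated B cells, rose 1.34-fold. Of the STAT3 targets 7 of 16 fell (7 over the list alone, 13 in the 22 libraries, camera adjusted p = 5.4e-07, median -0.50). SOCS3 (GRCh38 chromosome 17, 78356778 to 78360077) fell 5.23-fold (log2 fold change -2.39 ± 0.23, adjusted p = 9.2e-07), from 11.8 ± 1.49 to 2.26 ± 0.286 CPM. IL10 fell 2.26-fold (log2 fold change -1.18 ± 0.14, adjusted p = 1.6e-05), and MYC and PIM1, growth-promoting oncogenes, fell 1.65-fold and 1.84-fold. STAT3 itself had a log2 fold change of -0.45 (adjusted p = 0.31), which was -0.45 (adjusted p = 5.1e-10) in the 22 libraries. The B cell list had 6 of 24 down (7 over the list alone, 3 up and 16 down in the 22 libraries, camera adjusted p = 0.00024, median -0.14), POU2AF1 by 1.78-fold and CD22, an inhibitory coreceptor, by 1.81-fold. Interferon-response genes had 10 of 20 down (11 over the list alone, 3 up and 14 down in the 22 libraries, camera adjusted p = 1.1e-05, median -0.60), MX1 by 2.48-fold and IFIH1 by 3.30-fold.

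Cell cycle genes were lower at 24 h, with 5 of 20 mitosis genes down (8 over the list alone, 19 in the 22 libraries, camera adjusted p = 9.6e-07, median -0.43). Of 20 DNA replication genes 4 fell (4 over the list alone, 1 up and 16 down in the 22 libraries, camera adjusted p = 0.001, median -0.21, adjusted p = 0.15 with an estimated correlation in the 22 libraries). PLK1, a mitotic kinase, fell 1.62-fold (log2 fold change -0.70 ± 0.07, adjusted p = 1.0e-06). TPX2, a spindle assembly factor, fell 1.34-fold, and CDKN1A, the cell cycle inhibitor p21, rose 1.71-fold (log2 fold change 0.78 ± 0.08, adjusted p = 3.2e-06). Ribosome biogenesis and MYC targets had 1 of 21 up and 1 down (1 and 1 over the list alone, 1 and 13 in the 22 libraries, camera adjusted p = 0.029, median -0.19, adjusted p = 0.079 with an estimated correlation). That call ended without DMF 24 h replicate 2. Ferroptosis-related genes had 4 of 26 up and 2 down (9 and 3 over the list alone, 16 and 5 in the 22 libraries, camera adjusted p = 0.091, median 0.25), with ALOX5 down 2.54-fold. They were called higher in the 22 libraries, though not with an estimated correlation there (adjusted p = 0.079), and without control 12 h replicate 3. Log2 fold changes were -0.06 for GPX4 (adjusted p = 0.96), 0.11 for ACSL4 (adjusted p = 0.88) and -0.07 for TFRC (adjusted p = 0.92). They were -0.06 (adjusted p = 0.35), 0.11 (adjusted p = 0.028) and -0.07 (adjusted p = 0.29) in the 22 libraries. The glutathione list had 2 of 23 up and 2 down (2 and 2 over the list alone, 12 and 5 in the 22 libraries, camera adjusted p = 0.33, median 0.25). The iron list had 5 of 19 up and 2 down (5 and 2 over the list alone, 8 and 5 in the 22 libraries, camera adjusted p = 0.17, median 0.00). The lowest values among called genes included MYO7A, an unconventional myosin gene (9.54-fold; log2 fold change -3.25 ± 0.20, adjusted p = 4.3e-09), CX3CL1, the chemokine fractalkine (7.77-fold), and KCNA3, a potassium channel gene (6.20-fold).

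By edgeR's test 1048 genes were higher and 885 lower in DMF at 24 h, 317 and 277 at least 2-fold. For 63.9% of genes tested the DMF libraries lay on one side of the controls (10% for exchangeable libraries). In the 22 libraries 4010 were higher and 3795 lower, 495 and 369 at least 2-fold, and all 1933 calls kept their direction and side of the threshold. As at 6 h, the libraries compared were the same in both fits, so this does not test these calls. The myeloid marker CD68 rose 2.80-fold (log2 fold change 1.49 ± 0.28, adjusted p = 0.0013). It was 1 of 4 measured myeloid markers, whose mean log2 level against control at 6 h was -0.51 in control and -0.01 in DMF. Without control 12 h replicate 3 the counts were 1877 and 1700. Without replicate 1, 2 or 3 of control 24 h, 643, 656 or 605 genes were higher, and without replicate 1, 2 or 3 of DMF 24 h, 677, 666 or 668. On TPM, limma called 876 higher and 454 lower, 65.9% higher against 54.2%, and no longer called SESN2, PSAT1, GARS, MARS, HSPA1B, HSPA8, NFKBIA, TNFAIP3, CD83, MYC, PIM1, POU2AF1, PLK1, TPX2 and CDKN1A.

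At 48 h, the last time sampled, 19 of 28 NRF2 targets were higher and 2 lower (21 and 3 over the list alone, 23 and 4 in the 22 libraries, camera adjusted p = 1.7e-10, median 1.14). NQO1 rose 23.7-fold (log2 fold change 4.57 ± 0.22, adjusted p = 8.4e-11), from 3.41 ± 0.345 to 81.0 ± 1.74 CPM. HMOX1 rose 5.96-fold (log2 fold change 2.58 ± 0.14, adjusted p = 2.0e-10). FTL rose 6.39-fold (log2 fold change 2.68 ± 0.38, adjusted p = 2.6e-05), from 867 ± 62.8 to 5541 ± 259 CPM. SLC7A11 (GRCh38 chromosome 4, 138164097 to 138242349) rose 2.26-fold (log2 fold change 1.18 ± 0.25, adjusted p = 0.0014), from 3.69 ± 0.414 to 8.58 ± 1.28 CPM. MAP1A rose 35.8-fold (log2 fold change 5.16 ± 0.32, adjusted p = 1.2e-09). CYP4F11, a cytochrome P450 gene, had 0 counts in all 3 controls and 1.39 CPM in DMF, at least 47.6-fold higher against a floor of 3 counts over the group (0.0291 CPM). This floor covers counting error only. Heat shock genes had 10 of 20 up and 2 down (12 and 3 over the list alone, 15 and 4 in the 22 libraries, camera adjusted p = 0.00067, median 0.60, adjusted p = 0.22 with an estimated correlation in the 22 libraries), HSPA1B by 2.48-fold and DNAJA1 by 1.88-fold. Against control at 6 h the heat shock median at 48 h was -0.80 in control and -0.20 in DMF, so both were lower than at the start. The unfolded protein response list had 6 of 20 up (8 over the list alone, 15 up and 1 down in the 22 libraries, camera adjusted p = 0.0004, median 0.48), HSPA5 by 1.88-fold and DNAJB11 by 2.10-fold. Against control at 6 h this list's median at 48 h was -0.11 in control and 0.25 in DMF. HSPA5 stood at 682 to 683 CPM in control at 6 h. At 48 h it stood at 315 to 346 CPM in control and 621 to 645 CPM in DMF. The ATF4 list was mixed, with 10 of 35 up and 7 down (12 and 7 over the list alone, 17 and 13 in the 22 libraries, camera adjusted p = 0.36, median 0.04, with a mean of -0.01). In it SESN2 rose 1.58-fold (log2 fold change 0.66 ± 0.07, adjusted p = 7.1e-07). MARS rose 1.62-fold and JDP2 fell 3.05-fold (log2 fold change -1.61 ± 0.09, adjusted p = 4.3e-10). MARS stood at 243 to 257 CPM in control at 6 h. At 48 h it stood at 83.9 to 101 CPM in control and 141 to 162 CPM in DMF, so it was lower than at the start in both. SESN2 in DMF at 48 h (40.1 to 43.2 CPM) lay above control at 6 h (30.8 to 33.5 CPM).

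Ferroptosis-related genes had 11 of 26 up and 1 down at 48 h (11 and 1 over the list alone, 18 and 6 in the 22 libraries, camera adjusted p = 0.0071, median 0.33, adjusted p = 0.13 with an estimated correlation). GCLC and GCLM, the subunits of the enzyme that starts glutathione synthesis, rose 3.10-fold and 2.38-fold, and ALOX5 fell 3.51-fold (log2 fold change -1.81 ± 0.11, adjusted p = 1.4e-09). GCLC stood at 261 to 264 CPM in control at 6 h. At 48 h it stood at 79.0 to 80.5 CPM in control and 242 to 250 CPM in DMF. GCLM in DMF at 48 h (39.5 to 40.4 CPM) lay above control at 6 h (25.2 to 26.4 CPM). ALOX5 in control went from 4.34 to 4.62 CPM at 6 h to 17.1 to 18.7 CPM at 48 h, with 4.86 to 5.20 CPM in DMF. Log2 fold changes were -0.59 for GPX4 (adjusted p = 0.44), 0.25 for ACSL4 (adjusted p = 0.63) and -0.12 for TFRC (adjusted p = 0.8). They were -0.59 (adjusted p = 1.4e-09), 0.25 (adjusted p = 3.8e-05) and -0.13 (adjusted p = 0.033) in the 22 libraries. The glutathione list had 8 of 23 up and 2 down (9 and 2 over the list alone, 13 and 8 in the 22 libraries, camera adjusted p = 0.089, median 0.21). The iron list had 5 of 19 up and 4 down (5 and 4 over the list alone, 9 and 6 in the 22 libraries, camera adjusted p = 0.33, median 0.11). The glutathione list was called higher without control 48 h replicate 2.

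NF-kB targets were lower at 48 h, 19 of 30, with 3 higher (5 up and 22 down over the list alone, 6 up and 23 down in the 22 libraries, camera adjusted p = 1.2e-07, median -0.98). CD44, an adhesion receptor, fell 2.54-fold (log2 fold change -1.34 ± 0.07, adjusted p = 1.9e-10), from 739 ± 4.70 to 292 ± 0.774 CPM. NFKBIA fell 3.47-fold (log2 fold change -1.80 ± 0.14, adjusted p = 1.8e-08), from 106 ± 7.10 to 30.5 ± 0.999 CPM. TNFAIP3 fell 4.98-fold (log2 fold change -2.32 ± 0.36, adjusted p = 8.0e-05), and BIRC3, a caspase-regulating ubiquitin ligase, and BCL2L1, the survival gene BCL-XL, fell 3.84-fold and 2.74-fold. CCL4 rose 13.1-fold (log2 fold change 3.71 ± 0.22, adjusted p = 9.2e-10). CD83 rose 1.70-fold. STAT3 targets had 8 of 16 down (1 up and 8 down over the list alone, 1 and 12 in the 22 libraries, camera adjusted p = 1.6e-05, median -0.67). SOCS3 fell 6.82-fold (log2 fold change -2.77 ± 0.25, adjusted p = 1.0e-07), from 18.4 ± 0.705 to 2.76 ± 0.243 CPM. IL10 fell 3.20-fold (log2 fold change -1.68 ± 0.15, adjusted p = 1.5e-07), and MYC, PIM1 and PIM2 fell 2.03-fold, 2.86-fold and 1.98-fold. STAT3 had a log2 fold change of -0.21 (adjusted p = 0.64), which was -0.19 (adjusted p = 0.0002) in the 22 libraries. The B cell list had 11 of 24 down and 3 up (3 up and 12 down over the list alone, 3 up and 16 down in the 22 libraries, camera adjusted p = 0.00067, median -0.32), with CD22 down 3.05-fold and POU2AF1 2.63-fold. CD22 stood at 63.0 to 69.4 CPM in control at 6 h. At 48 h it stood at 202 to 207 CPM in control and 65.4 to 69.2 CPM in DMF.

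Hypoxia and glycolysis genes were lower than in control at 48 h, 10 of 20, with 1 higher (1 up and 11 down over the list alone, 3 up and 15 down in the 22 libraries, camera adjusted p = 0.00044, median -0.54, adjusted p = 0.22 with an estimated correlation in the 22 libraries). CA9, a carbonic anhydrase gene induced by hypoxia, fell 6.03-fold (log2 fold change -2.59 ± 0.37, adjusted p = 2.7e-05), from 69.8 ± 8.56 to 11.8 ± 2.01 CPM, and the glucose transporter gene SLC2A3 and the glycolysis regulator gene PFKFB4 fell 3.58-fold and 3.07-fold. Cholesterol synthesis genes had 6 of 22 down and 2 up (2 up and 6 down over the list alone, 2 up and 19 down in the 22 libraries, camera adjusted p = 0.0044, median -0.38), with LSS down 1.64-fold and INSIG1 down 1.62-fold. Mitosis genes had 11 of 20 down (11 over the list alone, 18 in the 22 libraries, camera adjusted p = 1.7e-05, median -0.49), PLK1 by 1.67-fold. DNA replication genes had 8 of 20 down (9 over the list alone, 3 up and 15 down in the 22 libraries, camera adjusted p = 0.0035, median -0.34, adjusted p = 0.22 with an estimated correlation in the 22 libraries), TYMS by 1.42-fold. The interferon list had 4 of 20 down and 1 up (1 up and 4 down over the list alone, 2 up and 8 down in the 22 libraries, camera adjusted p = 0.12, median -0.31). IFIH1 fell 4.30-fold (log2 fold change -2.11 ± 0.24, adjusted p = 2.3e-06). Among the lowest log2 fold changes were those of COLCA2 (31.7-fold, from 14.7 ± 1.18 to 0.417 ± 0.118 CPM), the iron-regulating protease gene TMPRSS6 (16.7-fold) and KCNA3 (16.6-fold). DUOX2, which encodes an enzyme that makes hydrogen peroxide, fell from 4.09 ± 0.564 to 0.0695 ± 0.0646 CPM (log2 fold change -5.31 ± 0.46). DUOX2 (GRCh38 chromosome 15, 45092650 to 45114344) overlaps DUOXA2 (chromosome 15, 45114321 to 45118421) at its end, and the strand used in counting was not stated, so both are uncertain.

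By edgeR's test 1785 genes were higher and 1680 lower in DMF at 48 h, 599 and 622 at least 2-fold. Of genes tested, 60.7% had the DMF libraries on one side of the controls (10% for exchangeable libraries). In the 22 libraries 4567 were higher and 4208 lower, 772 and 755 at least 2-fold, and all 3465 calls kept their direction and side of the threshold. The libraries of 48 h were again the same in both fits, so this does not test these calls. The myeloid marker CD68 rose 3.11-fold (log2 fold change 1.64 ± 0.29, adjusted p = 0.00031). Without control 12 h replicate 3 the counts were 2696 and 2602. On TPM, limma called 2193 higher and 788 lower, 73.6% higher against 51.5%, with a median log2 fold change of 0.217 over its 11655 genes against 0.015 over the 13419, so tool, scale, the use of TMM and genes differed. It no longer called MYC, PIM2, LSS, INSIG1, PLK1 and TYMS.

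**Figure D2:**
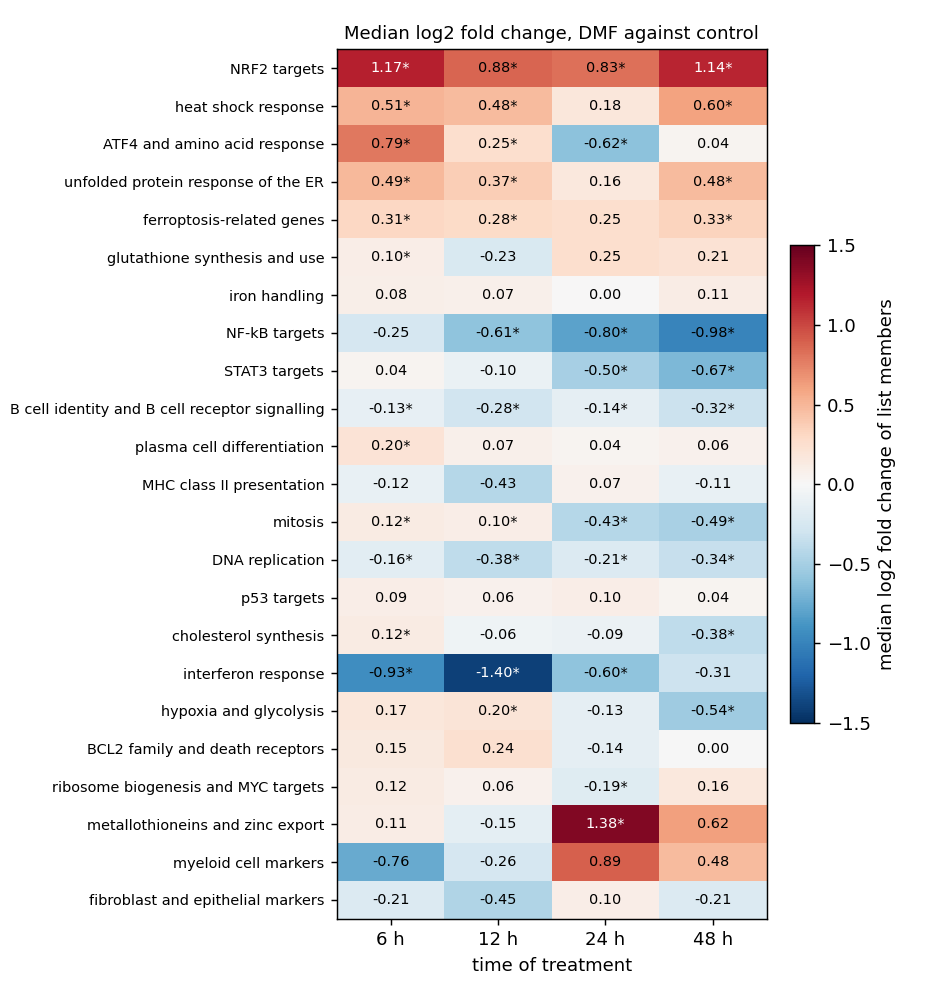
Median log2 fold change (DMF against control) of the measured members of each gene list, by time, with an asterisk for a camera adjusted p under 0.05. NRF2 targets stayed between 0.83 and 1.17, and NF-kB targets went from -0.25 to -0.98.

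**Figure D3:**
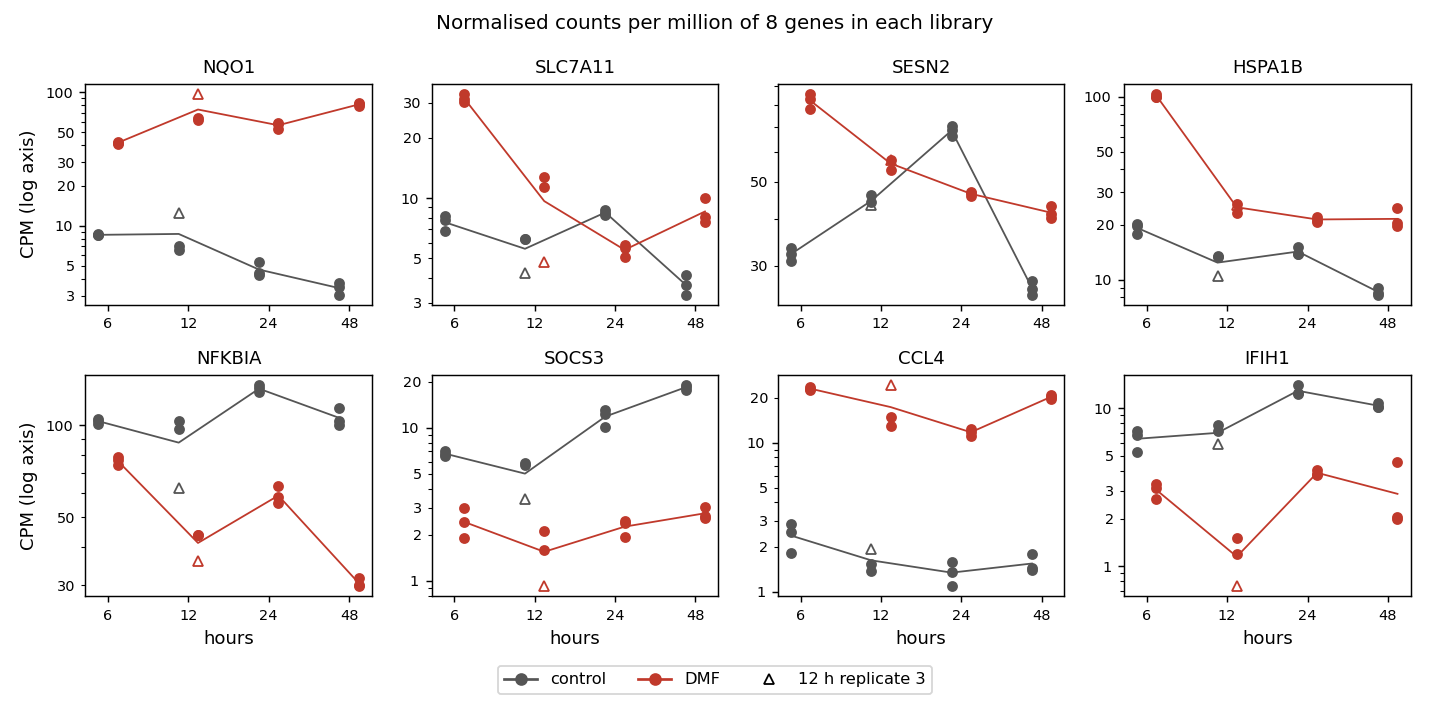
Normalised CPM (log axis) of 8 genes in each library by time in hours, control in grey and DMF in red, with lines through the group means and open triangles for replicate 3 of 12 h. NQO1 and CCL4 lay above control and NFKBIA and SOCS3 below it in the means of all 4 times, while SESN2 was above control at 6 h and below it at 24 h.

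Across times, 197 genes were higher and 187 lower in DMF at all 4 times, where independent lists would share 0.517 and 0.616. NQO1, HMOX1, OSGIN1, SRXN1 and CCL4 were among those higher, and SOCS3 among those lower. The comparisons at 6 and 12 h shared 456 higher and 489 lower genes (49.7 and 74.6 for independent lists), and those at 24 and 48 h shared 736 and 652 (139 and 111). Each time had its own control libraries, but all times shared a single estimate of the spread of each gene. Genes were therefore not equally easy to call, and the numbers for independent lists are no strict baseline. With the 22 libraries 2217 and 2048 were shared at 6 and 12 h (781 and 757 for independent lists), and 2708 and 2433 at 24 and 48 h (1346 and 1174). There 1030 genes were higher and 920 lower at all 4 times (77.2 and 65.3 for independent lists), and without control 12 h replicate 3 the numbers were 362 and 373.

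**Figure D4:**
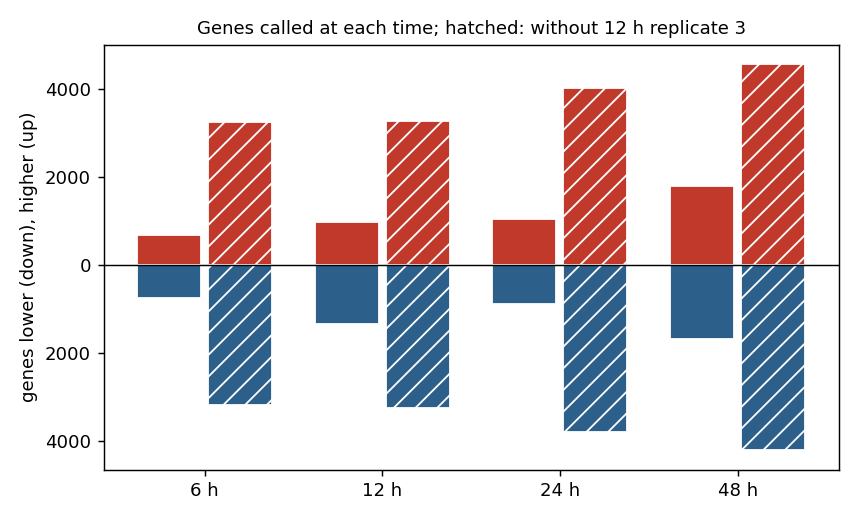
Number of genes called higher (upward bars) and lower (downward bars) in DMF at each time in hours by edgeR at an adjusted p under 0.05, for all 24 libraries (solid) and for the 22 without replicate 3 of 12 h (hatched). At 48 h the bars reach 1785 and 1680, and with the 22 libraries 4567 and 4208.

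The test of the difference between times asked which effects of DMF were not constant. Between 6 and 48 h the effect on the ATF4 list fell, by this test for 16 of 35 (1 up and 26 down over the list alone, 2 up and 32 down in the 22 libraries, camera adjusted p = 3.2e-14, median -0.81). SESN2 had log2 fold changes of 1.35 at 6 h, -0.56 at 24 h and 0.66 at 48 h, and its joint test over the 4 times gave an adjusted p of 4.7e-09. SESN2 in DMF at 24 h (45.8 to 47.1 CPM) lay above control at 6 h (30.8 to 33.5 CPM). NF-kB targets had a lower effect at 48 h than at 6 h, 4 up and 14 down of 30 (4 and 17 over the list alone, 4 and 23 in the 22 libraries, camera adjusted p = 3.7e-08, median -0.84). So did STAT3 targets, 1 up and 8 down of 16 (1 and 10 over the list alone, 2 and 14 in the 22 libraries, camera adjusted p = 6.1e-07, median -1.09). IL10, 1.68-fold higher at 6 h and 3.20-fold lower at 48 h, had a joint adjusted p of 7.2e-07. The effect was also lower at 48 h for mitosis genes, 9 of 20 (10 over the list alone, 19 in the 22 libraries, camera adjusted p = 8.3e-08, median -0.60). It was lower for cholesterol synthesis, 7 of 22 (8 over the list alone, 1 up and 21 down in the 22 libraries, camera adjusted p = 2.9e-06, median -0.50), and for hypoxia and glycolysis, 6 of 20 (7 over the list alone, 14 in the 22 libraries, camera adjusted p = 5.9e-06, median -0.58). For B cell genes the counts were 2 up and 6 down of 24 (2 and 7 over the list alone, 8 and 14 in the 22 libraries, camera adjusted p = 0.03, median -0.26), and for the BCL2 family and death receptors 1 up and 4 down of 21 (1 and 5 over the list alone, 5 and 10 in the 22 libraries, camera adjusted p = 0.033, median -0.31). It was higher for interferon-response genes, 4 up and 1 down of 20 (4 and 1 over the list alone, 9 and 2 in the 22 libraries, camera adjusted p = 0.033, median 0.49). All of these calls held with an estimated correlation, the B cell and interferon calls ended in the 22 libraries, that of hypoxia and glycolysis ended there with an estimated correlation (adjusted p = 0.12), and that of the BCL2 family ended without DMF 48 h replicate 2 or 3. For NRF2 targets the counts were 2 up and 3 down of 28 (5 and 7 over the list alone, 10 and 10 in the 22 libraries, camera adjusted p = 0.92, median 0.08), with camera's direction down.

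By edgeR's joint test the DMF effect differed between the 4 times for 2015 genes, and between 48 h and 6 h for 1657 (868 with a higher and 789 with a lower log2 fold change at 48 h). In the 22 libraries these counts were 9408 and 6929 (3632 higher and 3297 lower). They were 4087 and 3130 without control 12 h replicate 3, and the joint count was 3054 without DMF 12 h replicate 3. Between 12 and 6 h, 24 and 12 h, and 48 and 24 h the effect differed for 76, 743 and 419 genes, and in the 22 libraries for 1999, 5380 and 5605. Single libraries moved these 3 counts by more than 1.5 times. Without control 12 h replicate 3 they were 406, 1403 and 1307, and without DMF 12 h replicate 3 they were 132, 1697 and 684. The first was 38, 39 and 37 without control 6 h replicates 1, 2 and 3, and 43, 38 and 35 without DMF 6 h replicates 1, 2 and 3. It was 50 without control 24 h replicate 1 or 3 or control 48 h replicate 3, and 45 without DMF 12 h replicate 2. The count for 24 and 12 h was 403, 482 and 407 without control 24 h replicates 1, 2 and 3. It was 487, 445 and 444 without DMF 24 h replicates 1, 2 and 3, and 489 and 467 without DMF 12 h replicates 1 and 2. The count for 48 and 24 h was 263 and 233 without control 24 h replicates 1 and 3, and 278, 273 and 270 without DMF 24 h replicates 1, 2 and 3. It was 262 and 267 without control 48 h replicates 2 and 3, and 259 and 276 without DMF 48 h replicates 2 and 3.

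Control cultures also changed with time, which bears on any comparison at a late time. Genes described as rising or falling in DMF did so against control at the same time. PFKFB4 rose 43.5-fold in control between 6 and 48 h (log2 fold change 5.44 ± 0.26, adjusted p = 2.0e-11), from 3.41 ± 0.262 CPM to 148 ± 2.51 CPM, and stood at 48.1 ± 4.54 CPM in DMF at 48 h. NOXO1, which encodes an organizer subunit of NADPH oxidase, fell 20.9-fold (log2 fold change -4.38 ± 0.14, adjusted p = 1.7e-13). LAMP3, a lysosomal membrane protein gene, fell 19.1-fold. SLC2A9, a urate transporter gene, fell 26.2-fold. Few counts at 48 h set both of these folds. LAMP3 went from 1.57 to 2.08 CPM at 6 h to 0.0525 to 0.163 CPM at 48 h. For SLC2A9 the range was 1.24 to 1.87 CPM at 6 h and 0.0525 to 0.0654 CPM at 48 h. Against the control at 6 h, the median log2 level of hypoxia and glycolysis genes at 12, 24 and 48 h, and in DMF from 6 h on, was -0.26, 0.39 and 1.53 in control and 0.18, 0.11, 0.23 and 0.80 in DMF. For NF-kB targets these medians were 0.00, 0.31 and 0.59 in control and -0.24, -0.40, -0.21 and -0.35 in DMF. For STAT3 targets they were -0.25, 0.25 and 0.39 in control and 0.04, -0.28, -0.13 and -0.21 in DMF. For NRF2 targets they were -0.08, -0.28 and -0.29 in control and 1.14, 1.03, 0.71 and 0.62 in DMF, and for the ATF4 list 0.14, 0.38 and 0.01 in control and 0.79, 0.27, -0.07 and -0.19 in DMF.

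By edgeR's test 2522, 2257 and 5638 genes differed in control at 12, 24 and 48 h from 6 h, and 5393, 7687 and 10207 in the 22 libraries. The count at 12 h was 905, 908 and 815 without control 6 h replicates 1, 2 and 3, 4756, 4770 and 1435 without control 12 h replicates 1, 2 and 3, and 4143 without DMF 12 h replicate 3. The count at 24 h was 3760 without control 12 h replicate 3 and 1485 without control 24 h replicate 2.

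**Figure D5:**
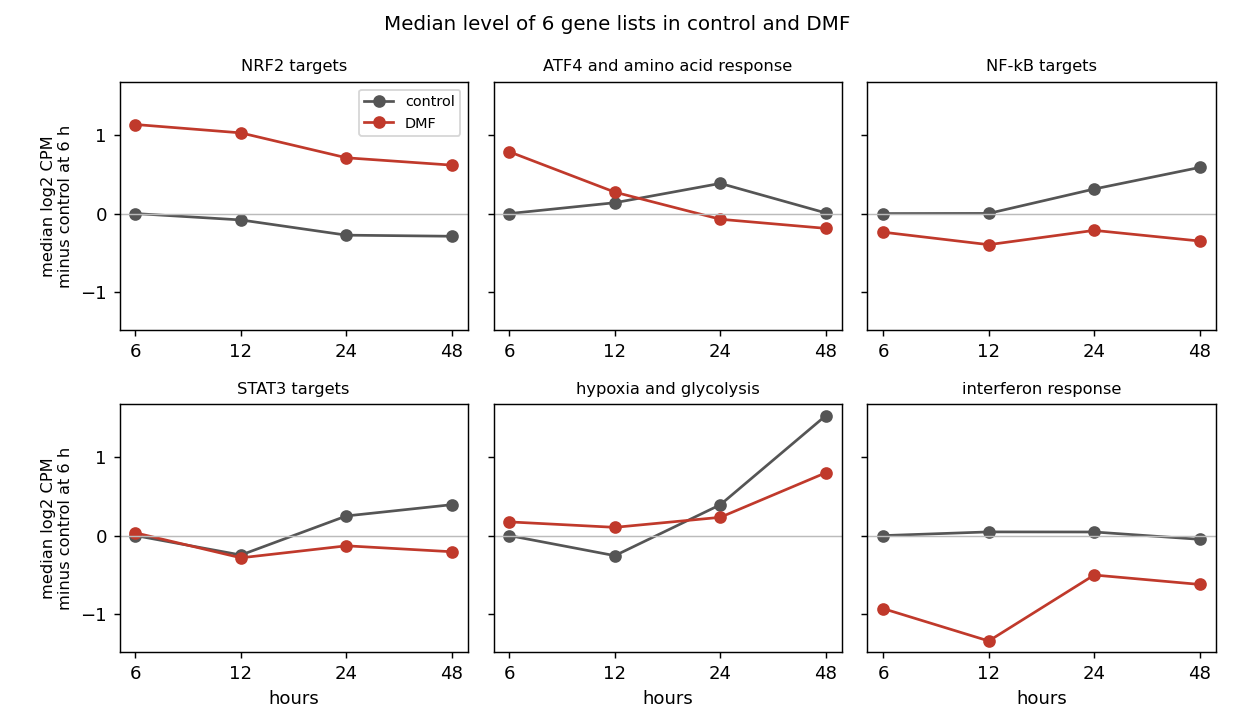
Median log2 level of the members of 6 gene lists relative to control at 6 h, by time in hours, in control (grey) and DMF (red). Hypoxia and glycolysis genes rose to 1.53 in control and 0.80 in DMF at 48 h.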

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

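Every split of the libraries and each explanation in this part was tested only after the result was seen. What singled out the following results was a difference between groups: the effect of DMF was not the same at all times. By camera on the difference of effects, 48 h minus 6 h, the median log2 difference was -0.81 for the ATF4 list, -0.84 for NF-kB targets, -1.09 for STAT3 targets, -0.26 for B cell genes, -0.60 for mitosis, -0.50 for cholesterol synthesis, -0.58 for hypoxia and glycolysis, -0.31 for the BCL2 family and death receptors, and 0.49 for interferon-response genes.

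Among the 32 panel genes, the joint test over the 4 times gave an adjusted p of 1.2e-06 for ATF3, 0.0003 for CD83, 2.1e-06 for CHAC1, 1.7e-05 for DNAJB1, 0.0021 for GCLM, 0.022 for HMOX1, 7.2e-07 for HSPA1B and 7.2e-07 for IL10. It was 0.0042 for IL6, 3.3e-06 for MYC, 0.00047 for NFKBIA, 0.00011 for NQO1, 0.00023 for PIM1, 0.00015 for SLC7A11, 0.024 for SOCS3 and 2.2e-05 for SRXN1.

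The counts of genes behind these differences were compared with other splits of the same libraries. For the difference between 48 and 6 h (1657 genes), 1 of 100 splits, the real one, gave as many, with a highest other count of 1017. For the joint test (2015 genes) it was 9 of 100, highest 3857, for 12 against 6 h (76) 15 of 100, highest 2574, for 24 against 12 h (743) 20 of 100, highest 5220, and for 48 against 24 h (419) 8 of 100, highest 1288. Such splits cannot decide whether the effect differs between times, because they can keep the effect of DMF at 1 time and lose it at another. For 48 and 6 h, 48 and 24 h and the joint test, all 17, 17 and 22 other splits with any gene kept the real groups at a time compared, and those that did not gave 0 by edgeR. For DMF against control at 6, 24 and 48 h (1425, 1933 and 3465 genes), and for control at 12, 24 and 48 h against 6 h (2522, 2257 and 5638), only the real split of 10 gave as many and the highest other gave 0 by edgeR. With 10 splits no share under 0.05 is possible. At 12 h (2324 genes) 5 of 10 splits gave as many, the highest 7707, because splits that put both replicate 3 libraries on one side measure how these differ.

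At 48 h several lists were lower in DMF than in a control that had itself changed with time, so the control's change is an alternative to a loss in DMF. If it accounts for the difference, the list median of DMF at 48 h minus control at 6 h should lie at or above 0. It was 0.80 for hypoxia and glycolysis (95% interval from 2000 bootstrap draws 0.39 to 1.39) and 0.35 for cholesterol synthesis (0.22 to 0.66), as that explanation predicts. A value at or above 0 would also arise if DMF lessened a rise with time, so it cannot tell these apart. For NF-kB targets it was -0.35 (-0.74 to 0.20) and for STAT3 targets -0.21 (-0.72 to 0.31), which cannot decide. For mitosis it was -0.47 (-0.65 to -0.38), and control at 48 h had a median of 0.00 against control at 6 h. The control median thus did not rise for this list. The value of -0.47 therefore restates the difference from control at 48 h and is no separate test. These intervals came from draws over the genes of a list, so they do not measure spread between libraries. No biological explanation was tested.

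CCL3 and CCL4 were higher in DMF at all times, although the NF-kB list was lower from 12 h on. Shared reads between near-identical copies were excluded as the cause: the summed counts of a gene and its copy (CCL3L3, CCL4L2) had a lowest log2 ratio of 2.60. The folds of the sums at 6, 12, 24 and 48 h were 9.60, 6.07, 7.39 and 11.4 for CCL3, and 9.41, 9.99, 7.81 and 11 for CCL4. In each case all DMF libraries lay above all controls.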

How the results depend on the processing

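The fits without replicate 3 of 12 h, the nested block and the library weights were chosen after seeing the data, while the other alternatives were fixed in advance. No named gene changed direction where it had a call, and neither did any list in the fits where lists were tested. Lists were not tested on TPM, with DESeq2, with library weights, with the nested block or with only the groups compared. Nor were they tested with a replicate block without the pair. Balances of counts did change, as at 12 h, where lower genes outnumbered higher ones with all libraries but not without the pair. Depth limits replicate 1 of DMF at 48 h, and its removal beside the pair moved little. In what follows, counts come in the order 6, 12, 24 and 48 h for genes higher and lower in DMF, then genes called at all times, then differences between times (joint, 12 and 6 h, 24 and 12 h, 48 and 24 h, 48 and 6 h), then control at 12, 24 and 48 h against 6 h. In the fit of all libraries they were 675, 989, 1048 and 1785 higher, 750, 1335, 885 and 1680 lower, 197 and 187 at all times, 2015, 76, 743, 419 and 1657 for differences between times, and 2522, 2257 and 5638 in control. Where no cause is named, the cause was not tested.

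Without the replicate 3 pair of 12 h, counts were 3242, 3277, 4010 and 4567 higher, 3179, 3238, 3795 and 4208 lower, 1030 and 920 at all times, 9408, 1999, 5380, 5605 and 6929 for differences between times, and 5393, 7687 and 10207 in control. Without the shallow 48 h library as well, they were 3252, 3296, 4020 and 4518 higher, 3189, 3257, 3798 and 4094 lower, 1035 and 922 at all times, 9360, 2028, 5429, 5518 and 6888 for differences between times, and 5415, 7713 and 10204 in control. Without the pair and with a replicate block they were 3220, 3256, 3977 and 4504 higher, 3160, 3210, 3791 and 4187 lower, 1012 and 906 at all times, 9313, 1952, 5296, 5592 and 6892 for differences between times, and 5143, 7623 and 10191 in control. DESeq2 without the pair gave 3173, 3135, 3658 and 4243 higher, 2845, 2931, 3611 and 3968 lower, 972 and 803 at all times, 8853, 1861, 5019, 5146 and 6439 for differences between times, and 4884, 7214 and 9795 in control. With limma voom and library weights (0.00843 and 0.017 for the pair) they were 3710, 3480, 4232 and 4407 higher, 3708, 3592, 4098 and 4187 lower, 1146 and 1076 at all times, 9870, 2902, 5976, 5611 and 7226 for differences between times, and 5941, 8563 and 10100 in control. A replicate block nested in time gave 2342, 3133, 3196 and 3782 higher, 2446, 3278, 3138 and 3643 lower, 709 and 670 at all times, 8128, 1272, 5248, 3729 and 5398 for differences between times, and 1865, 4092 and 7425 in control. Lists called higher at 24 h numbered 4 without the pair, with or without the shallow library, against 2. Of the named genes' results, 33 gained a call and none lost one without the pair, and 4 list calls ended and 6 began. At 6, 24 and 48 h the libraries compared were the same with and without the pair, so gene calls kept there were not tested by it.

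With only the groups compared in the fit, edgeR gave 3614, 0, 3951 and 3884 higher, 3642, 0, 3866 and 3851 lower and 0 and 0 at all times. Differences between 2 times were 1, 30, 5030 and 6660, and control counts 0, 8418 and 9531. The 0 at 12 h came with 1109 genes at an unadjusted p under 0.05 for DMF and 1245 for control, where DESeq2 on all libraries called 2764 and 3599. That follows from 6 or 12 libraries with the pair among them. Of the named genes' results 47 lost their call, all at 12 h, and 22 gained one.

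On TPM, limma gave 240 and 377 higher at 6 and 12 h, 795, 454 and 788 lower at 12, 24 and 48 h, 105 and 98 at all times, 27 for 12 and 6 h, and 974 and 1415 for control at 12 and 24 h. There 70 results of named genes lost their call and 8 gained one, and the cause was not tested. Of the 2522 genes called in control at 12 h, 493 changed the sign of their log2 fold change on TPM, where 282 were called higher and 692 lower, against 1604 and 918. At 48 h 20 of 3465 did so, and 43 of 1657 for 48 and 6 h. DESeq2 on all libraries gave 322, 1253 and 857 for 12 and 6 h, 24 and 12 h, and 48 and 24 h, and 4 named genes gained a call. Without a low-count filter the count for 12 and 6 h was 43, and 7 named calls ended, with more genes tested. DESeq2's size factors in edgeR moved no count by over 1.5 times, ended 2 gene calls (MYC at 12 h, DNAJB1 at 24 h) and the B cell and mitosis calls at 6 h. With an estimated correlation, camera called 4 lists higher at 12 h and 1 lower at 6 h, against 7 and 3. In all, 9 list calls ended: glutathione, B cell, mitosis and DNA replication at 6 h, ferroptosis, mitosis and hypoxia at 12 h, ribosome biogenesis at 24 h and ferroptosis at 48 h. All other list calls held. Without the pair and with an estimated correlation, 1 list was higher at 24 h and 2 at 48 h. There 18 list calls ended: glutathione, plasma cell, mitosis, DNA replication and cholesterol synthesis at 6 h, ATF4, mitosis and hypoxia at 12 h, DNA replication, ribosome biogenesis and metallothioneins at 24 h, heat shock, ferroptosis, DNA replication and hypoxia at 48 h, and B cell, interferon and hypoxia for 48 minus 6 h. The iron list gained a call at 6 and 12 h. Fry, which tests a list by itself, called 7 lists higher at 24 h and 10 at 48 h, and 25 list calls began.

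With 1 library left out, genes higher numbered 480 to 1242, 757 to 2194, 605 to 1877 and 1336 to 2696 at 6, 12, 24 and 48 h and genes lower 482 to 1403, 954 to 2367, 640 to 1700 and 1333 to 2602. Genes called at all times numbered 148 to 362 and 139 to 373. Differences between times numbered 1578 to 4087, 35 to 406, 403 to 1697, 233 to 1307 and 1275 to 3130, and control counts 815 to 4770, 1485 to 3760 and 4764 to 7503. Lists higher at 24 h numbered 2 to 4. In the group that lost a library, its 2 others carried the mean and all groups the spread. Over the 24 such fits, 127 results of named genes and 38 of lists lost a call, and 41 and 9 gained one.

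Replicate numbers were not taken to pair the samples, as not every pair of libraries deviated together. Over 8853 genes, the 12 pairs of control and DMF deviations with the same number and time had correlations of -0.184 to 0.98, 4 of 12 were over 0.1, and 5 of 12 controls correlated best with their own number. The 3 pairs of 12 h had 0.961, 0.968 and 0.98, as the replicate 3 libraries deviated alike, but control replicate 1 and DMF replicate 2 also had 0.96, so pairing was not settled at that time. With a replicate block, 695 genes were higher and 782 lower at 6 h and 2083 differed in the joint test, and no count moved by over 1.5 times. With the block nested in time, 6411 genes were called at 12 h against 2324, among them ACSL4 and TFRC (log2 fold changes 0.37 and 0.43), which had no call with all libraries and no block.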

Other observations

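Predictions for GC content and for exchanged labels were written before their values were seen, and every other test in this part was chosen after the result was seen. Some lists were called at no time by camera. For the 23 measured p53 targets, median log2 fold changes at 6, 12, 24 and 48 h were 0.09, 0.06, 0.10 and 0.04 (camera adjusted p = 0.13, 0.34, 0.49 and 0.26). Of these, 6 up and 3 down were called at 48 h. TIGAR, which lowers glycolytic flux, rose 2.50-fold (log2 fold change 1.32 ± 0.11, adjusted p = 2.7e-08), and BBC3, which encodes the death effector PUMA, fell 3.40-fold (log2 fold change -1.77 ± 0.25, adjusted p = 2.3e-05). TIGAR stood at 49.5 to 54.1 CPM and BBC3 at 1.19 to 1.72 CPM in control at 6 h. At 48 h TIGAR stood at 12.0 to 14.4 CPM in control and 31.9 to 33.7 CPM in DMF. BBC3 then stood at 13.7 to 17.3 CPM in control and 4.26 to 4.88 CPM in DMF. For the 21 genes of the BCL2 family and death receptors the medians were 0.15, 0.24, -0.14 and 0.00 (camera adjusted p = 0.41, 0.94, 0.17 and 0.26). For MHC class II presentation (12 genes) they were -0.12, -0.43, 0.07 and -0.11 (camera adjusted p = 0.21, 0.092, 0.88 and 0.77), with camera's direction up at 24 h against a mean of -0.11, and the list was called lower at 12 h without control 12 h replicate 1 or 2 or DMF 12 h replicate 3. HLA-DQA1 fell 2.20-fold and its regulator CIITA rose 1.59-fold at 48 h.

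Other lists were called at some times only. Plasma cell genes at 12, 24 and 48 h had medians of 0.07, 0.04 and 0.06 (camera adjusted p = 0.28, 0.91 and 0.79), with means of -0.14, -0.09 and -0.17 and camera directions up, down and up. SDC1, which encodes the plasma cell marker CD138, fell 3.46-fold at 48 h, while SLAMF7 rose 2.13-fold. Cholesterol synthesis genes had medians of -0.06 and -0.09 at 12 and 24 h (camera adjusted p = 0.95 and 0.19). Hypoxia and glycolysis genes had 0.17 and -0.13 at 6 and 24 h (camera adjusted p = 0.15 and 0.47), and were called higher at 6 h in the 22 libraries, though not with an estimated correlation there (adjusted p = 0.37). Ribosome biogenesis genes had 0.12, 0.06 and 0.16 at 6, 12 and 48 h (camera adjusted p = 0.41, 0.16 and 0.39). Metallothioneins had 0.11, -0.15 and 0.62 (camera adjusted p = 0.71, 0.84 and 0.35), with camera's direction up at 12 h. The median at 12 h includes the replicate 3 libraries, where MT1X and MT2A were lower in DMF than in control. In replicates 1 and 2 of 12 h these genes were higher in DMF.

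Markers of T, NK, myeloid, fibroblast and epithelial cells were low. The 4 measured myeloid markers gave camera adjusted p-values of 0.29, 0.95, 0.17 and 0.77 at the 4 times, and the 3 fibroblast and epithelial markers 0.67, 0.34, 0.29 and 0.27. The myeloid median at 12 h was -0.26 with camera's direction up, and that of the second list at 24 h was 0.10 with a mean of -0.34. Only 2 T and NK cell markers were measured, too few for a list test, with CD8A at 0.882 CPM at most. CD8A was called lower at 48 h (log2 fold change -1.29, adjusted p = 0.031), but without any 1 of the 6 libraries of 48 h it was not (-1.18 to -1.5). CD68 reached 8.90 CPM (DMF 48 h replicate 3) and EPCAM 4.02 CPM (control 48 h replicate 2). EPCAM fell at 24 h (log2 fold change -1.38, adjusted p = 3.5e-05) and 48 h (-1.23, adjusted p = 8.7e-05). No mitochondrially encoded mRNA was among the genes tested, and that list was not analysed here.

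Why the replicate 3 libraries of 12 h stood apart was tested across 8853 genes, as the deviation of each library from the other 2 of its group. It correlated with log2 effective length at r = -0.725 in control and -0.758 in DMF. A cubic fit on log2 effective length took up 53.7% and 59% of variance, so a loss of reads from long transcripts may account for part of it. GC content gave 0.549 and 0.524 (99.1% of genes). Partial correlations were -0.743 and -0.773 for length given GC and 0.572 and 0.55 for GC given length, so neither could replace the other. Exchanged labels were excluded, as the DMF minus control difference of the pair correlated with that of replicates 1 and 2 at r = 0.658, and RNA from T, NK, myeloid, fibroblast or epithelial cells was excluded, with no marker over 4.75 CPM before TMM scaling (CD68, at 7.55 CPM after it), while a biological cause was not tested.

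A further hypothesis was that DMF cultures changed less with time than control cultures. Among the 1000 genes with the most change in control from 6 to 48 h, chosen on other libraries than those measured, the slope of the change in DMF on that in control was 0.689 (95% interval 0.662 to 0.715). Choice on control lowers such a slope by itself, and with 991 genes chosen on DMF the slope of control on DMF was 0.754 (0.718 to 0.788). With 789 genes chosen on both alike, the ratio of root mean square changes, DMF to control, was 0.928 (0.897 to 0.959). The hypothesis asked for a ratio under 0.9, a bound within this interval, so it was not decided. These intervals came from bootstrap draws over genes and do not measure spread between libraries.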
